A study of Mus musculus with 8 samples.

How the data were processed

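RNA was measured in hematopoietic stem cells (HSCs) from the bone marrow of C57BL/6J mice. Per the labels' protocols, marrow was depleted of lineage-positive cells, stained for CD150, CD48, Sca-1 and CD117 (the products of Slamf1, Cd48, Ly6a and Kit), and sorted by scatter. Each of the 8 libraries came from 10000 cells sorted in G0/1 phase, and cDNA was made with a low-input kit. The 4 groups, Small, Medium, Large and All (not fractionated by size), have 2 libraries each. Groups and replicate numbers come from the sample titles. The labels do not say that the 2 libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical. HSCs from mice given PD, rapamycin or vehicle, which the series design also names, were not analysed here.

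The submitters' processing notes list STAR 2.5.3a, RSEM 1.3.0, SAMtools 1.3 and the genome build mm10; the annotation release is not given in the sources used here. The authors deposited a table of estimated counts per gene, already rounded to whole numbers and not scaled between libraries. They also deposited log2(TPM + 1) values, in which the TPM values (transcript abundances scaled to a fixed total) add up to 1000000 in each library. Total counts ran from 13698362 in Small 2 to 16838448 in All 2. A count of 3, taken as the floor for a gene at 0, is 0.178 to 0.219 CPM (counts scaled to a library total of 1000000) over the libraries before TMM scaling. Fold bounds for genes at 0 in Small used a floor of 0.204 CPM. Floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Of the 50686 Ensembl gene IDs, 50376 matched a symbol in the GENCODE M21 annotation of GRCm38 (the same assembly as mm10), and the 310 others held at most 0.131% of a library's counts. Coordinates are those of that annotation. Counts are per gene over its exons, so reads shared by near-identical genes, such as immunoglobulin variable segments, histones, ribosomal protein genes and the hemoglobin beta copies Hbb-bs and Hbb-bt, were split by estimation and are uncertain. The sources used here do not state whether counting used strand.

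The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the counts, with TMM scaling, robust estimation, and group as the only term over all 8 libraries, which leaves 4 residual degrees of freedom. The filterByExpr function with a minimum count of 10 kept 16066 genes. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. CPM values are scaled by TMM. They are relative to the other genes of a library, so higher and lower refer to relative abundance and not to amounts per cell. RNA per cell, which may differ with cell size, was not measured. Means are given ± SD with n = 2, and fitted log2 fold changes with their standard error (SE). An exact test of 2 against 2 samples cannot give a two-sided p under 0.333. Both libraries of one group lie above both of another for 16.7% of genes by chance, and in either direction for 33.3%. These shares assume that the libraries are interchangeable, which differences between the replicate numbers break.

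The 29 gene lists hold 663 genes, of which 16 had no tested gene. They cover the sort markers, HSC identity, multipotent progenitors, megakaryocytes and platelets, aged HSCs, G1/S and G2/M phase, cell cycle inhibitors and quiescence, p53 targets, ribosomal proteins, ribosome biogenesis, nuclear and mitochondrial genes of oxidative phosphorylation, glycolysis, fatty acid oxidation, cholesterol synthesis, lysosome and autophagy, the integrated stress and unfolded protein responses, immediate early genes, interferon response, actin cytoskeleton, histones, and markers of erythroid, granulocyte and monocyte, macrophage and dendritic, B, T and NK, mast, basophil and eosinophil, and endothelial and stromal cells. Lists with at least 5 tested genes, 28 in all, were compared with all other genes by limma's camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. Some lists share genes: Slamf1, Neo1 and Sult1a1, for example, are in both the HSC identity and the aged HSC list. Camera was repeated with an estimated correlation. List medians with all 8 libraries are of fitted log2 fold changes, and those under alternatives are of log2 CPM, on which the medians with all libraries can differ (for macrophage and dendritic genes in Large against Small, -0.67 in place of -0.44). The fry test, also run, asks whether a list's genes move on balance one way and does not compare them with other genes.

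Genes were named by a rule. Among genes past the threshold with a mean of at least 5 CPM, a symbol that is not a Gm, Rik or pseudogene name, and both libraries of one group above both of the other, it takes the largest fold changes in each direction. Where none passes, it takes the 2 genes with the smallest unadjusted p in each direction, named as not past the threshold. It adds up to 4 members of each list with the smallest unadjusted p in Large against Small, and always Kit, Ly6a, Slamf1, Cd48 and Mki67. Other genes in the text were chosen after their values were seen. Some genes that the rule names are not reported here. The position of Medium between Small and Large was to be taken over genes called in Large against Small; with 0 genes called it has no value. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined.

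Alternatives fixed with the design were DESeq2 size factors or library totals in place of TMM; no filter (28543 genes) or at least 10 CPM in 2 libraries (10283 genes); DESeq2 1.42.0, limma-voom, and limma-trend on the deposited log2(TPM + 1) values; only the 4 libraries of a pair; the replicate number as a block (3 residual degrees of freedom); leaving out each library in turn; and the estimated correlation and fry. Leaving out a library leaves 1 in its group, which is then assumed to vary like the other groups. The fits without 1 library have no term for the replicate number. The group left with 1 library holds 1 number while the others hold both, so differences between the numbers enter its comparisons. Alternatives chosen after seeing the data were DESeq2 and limma-voom with the block, edgeR with the block at an adjusted p under 0.1, the removal of each library's lowess trends (span 0.3) with GC content and transcript length with and without the block, the 2 other list tests with the block, and 2 other scalings for the lists.

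Libraries with the same replicate number deviated together. The correlation across genes of their deviations from the group means was 0.358 to 0.439 over the 6 pairs of groups, above 0.1 in all 6. The main fit has no term for this, and fits with the number as a block, which pair the libraries, are given beside it. This pairing comes from the data and not from the labels, and it was settled after the calls of both fits had been seen. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 71.9 to 181), so each was counted as 1 sample.

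The procedure was tested on simulated data for Large against Small, in 5 simulations of 16066 genes with the replicate-number differences of the real libraries and 200 genes changed. The edgeR fit recovered 0.299% of genes changed 2-fold, 18.2% of those changed 4-fold and 57.9% of those changed 8-fold, with 0 false calls among 253. DESeq2 recovered 5.08%, 66.0% and 93.6%, with 5.53% of its calls false. With the block, edgeR recovered 39.4%, 85.7% and 95.5% with 9.38% false calls, and DESeq2 52.8%, 90.8% and 99.1% with 23.3% false calls. Camera with the preset correlation found a list shifted by a log2 change of -0.75 in 5 of 5 simulations and called 0 of 135 unshifted lists. Apart from the replicate-number differences, the simulated genes varied independently. In the real libraries, without the block, the estimated correlation within a list was as high as 0.92 for G2/M and 0.95 for granulocyte and monocyte genes. With the block these were 0.68 and 0.85, and it was 0.02 for ribosome biogenesis and 0.12 for interferon response genes. The simulations therefore do not measure how often camera with the preset correlation calls unshifted lists in these data. With an estimated correlation it found the shifted list in 0 of 5. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.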

Results

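Hematopoietic stem cells (HSCs) are the marrow cells that maintain all blood lineages, and the comparison addresses how their gene expression differs with cell size. Small and Large HSCs were the 10% of cells at the lower and upper end of the size distribution. Medium HSCs lay within 10% of the mean size, and All HSCs were not separated by size. Each group had 2 libraries, numbered 1 and 2. Total counts were 15896952 and 13698362 for Small 1 and 2, 15298376 and 15742594 for Medium, 15138852 and 15585024 for Large, and 14745907 and 16838448 for All.

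The libraries separated first by replicate number. The first principal component held 39.5% of the variance and placed the 4 libraries numbered 1 between -81.2 and -31.1 and the 4 numbered 2 between 0.984 and 106. On the second component (15.6% of the variance) All 2 lay highest, at 69.4, and Small 2 lowest, at -62.2, with the others between -30.4 and 29.8. Large 2, at 0.984 on the first component, was about as close to both numbers. It correlated with libraries numbered 1 at 0.940 to 0.946 and with those numbered 2 at 0.908 to 0.944. Among the sort antigens, Kit, the receptor for stem cell factor, had 606 ± 132 CPM in Large and 1024 ± 244 in Small (log2 -0.76, SE 0.31). Ly6a, which encodes Sca-1, had 103 ± 117 and 167 ± 171 CPM, with both libraries numbered 1 at 20.4 and 45.7 CPM and both numbered 2 at 186 and 288. Slamf1 (CD150) had 9.51 ± 2.73 and 9.77 ± 1.5 CPM, and Cd48 had 132 ± 38.1 and 99.2 ± 51.7. None of these 4 genes passed the edgeR test (adjusted p = 0.975 for Kit, Ly6a and Cd48 and 0.998 for Slamf1). Markers of granulocytes and monocytes were abundant and uneven: their summed expression was 51043 and 14993 CPM in Small 1 and 2, 28516 and 10525 in Medium, 49895 and 26476 in Large, and 66293 and 4936 in All.

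**Figure D1:**
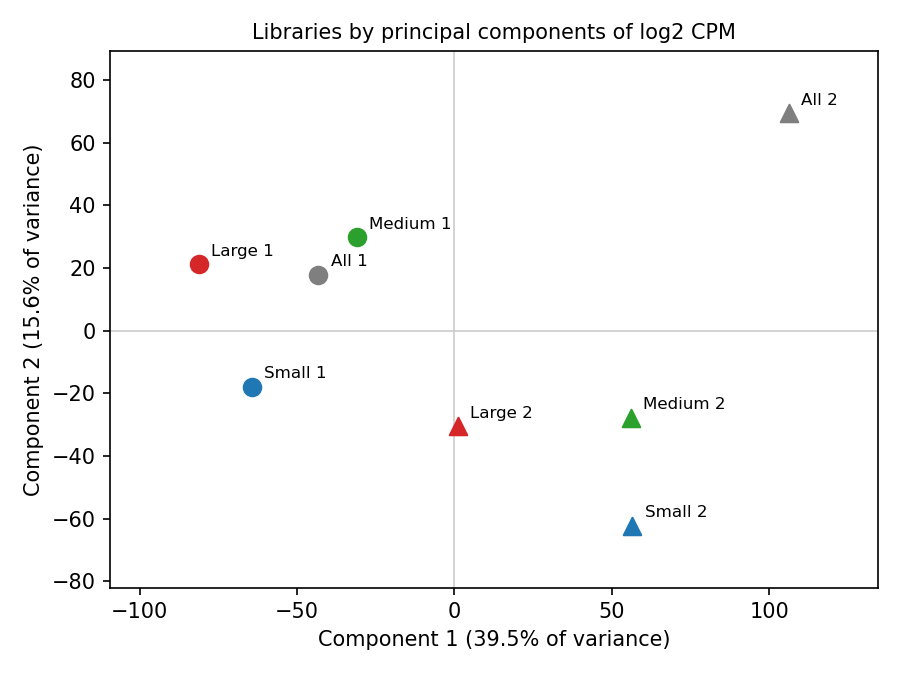
Each point is a library placed by the first principal component of log2 CPM (horizontal, 39.5% of the variance) and the second (vertical, 15.6%), coloured by size gate, with circles for replicate number 1 and triangles for number 2. The 4 libraries numbered 1 lie left of the 4 numbered 2. All 2 lies apart at 106 and 69.4, and Small 2 lies lowest on the second component, at -62.2.

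Transcripts of DNA replication and mitosis genes had a higher relative abundance in Large than in Small HSCs, although per the labels all cells were sorted in G0/1 phase. Granulocyte and monocyte genes as a list moved with them within number 2 (median 0.82) but not within number 1 (-0.37), while its 5 primary granule and progenitor genes, grouped after the values were seen, moved with them in both (0.82 within number 1 and 1.1 within number 2). Mpo, the most abundant of these, had 16527 and 7201 CPM in Large 1 and 2 and 13617 and 3462 in Small 1 and 2. The G1/S list was higher in Large, with a median log2 difference of 0.81 (0.54 within number 1 and 1.22 within number 2; camera adjusted p = 2.7e-08, and 0.87 with an estimated correlation). Of its 30 members, 24 had both Large libraries above both Small libraries, against 16.7% by chance. Pcna, the sliding clamp of DNA polymerase, had 588 ± 40.6 CPM in Large and 305 ± 71.5 in Small (log2 0.95, SE 0.33), and the replicative helicase subunit Mcm7 had 681 ± 23.7 and 385 ± 133. The G2/M list was also higher, by a median of 0.84 (0.49 and 1.34; adjusted p = 0.00016, and 0.87 with an estimated correlation), with 23 of 24 members higher in Large within both numbers, against 32.9% of all genes, and 13 of 24 with both Large libraries above both Small libraries. Cenpe, a kinesin of the kinetochore, had 19.7 ± 13.2 and 3.48 ± 2.6 CPM (log2 2.49, SE 1.01). Top2a had 352 ± 67.4 and 156 ± 78.9 CPM, and the proliferation marker Mki67 had 39.7 ± 29.7 and 12.0 ± 2.16 (log2 1.73, SE 0.90). No single member passed edgeR's test when adjusted over the list alone, in either list, but with the replicate number as a block 21 of 30 G1/S and 7 of 24 G2/M genes did. Both list calls were thus lost with an estimated correlation. The G2/M call also ended without Small 2 (median 0.27) or without Large 1 (0.68). G2/M genes were higher in number 1 than in number 2 (median 1.49), which lowers the median in both fits.

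Genes of protein synthesis and respiration were higher in Large than in Small as well. Primary granule and progenitor genes moved with them (0.82 within number 1 and 1.1 within number 2). The whole granulocyte and monocyte list did so only within number 2 (-0.37 and 0.82). Cytosolic ribosomal proteins had a median log2 difference of 0.44 (0.42 and 0.46; adjusted p = 4.6e-19, and 0.87 with an estimated correlation), and 74 of 79 members had both Large libraries above both Small libraries. Rplp1, of the ribosomal stalk, had 281 ± 37.7 CPM in Large and 180 ± 23.7 in Small (log2 0.64, SE 0.19), and Rpsa had 803 ± 122 and 516 ± 26.2. Nuclear genes of oxidative phosphorylation were higher by a median of 0.49 (0.38 and 0.66; adjusted p = 1.7e-10, and 0.87 with an estimated correlation), and 54 of 54 were higher within both numbers, 17 of them with both Large libraries above both Small libraries. Cox4i1, a subunit of cytochrome c oxidase, had 444 ± 83.6 and 313 ± 79.0 CPM, and Ndufa4 had 421 ± 70.4 and 261 ± 81.0. Ribosome biogenesis genes were higher by a median of 0.32 (0.34 and 0.30; adjusted p = 0.00013, and 0.87 with an estimated correlation), 24 of 28 of them within both numbers and 10 with both Large libraries above both Small libraries. The box C/D snoRNP protein Nop58 had 226 ± 25.9 and 137 ± 7.87 CPM, and Dkc1, the pseudouridine synthase dyskerin, had 248 ± 66.2 and 133 ± 26. The 13 mitochondrially encoded genes did not pass (median 0.08; 0.55 within number 1 and -0.34 within number 2; adjusted p = 0.48). With trends in GC content and transcript length removed, the mitochondrially encoded list was called lower (-0.42, adjusted p = 0.022, and 0.040 with the replicate block). In each of the 3 called lists 0 members passed edgeR when adjusted over the list alone. With the replicate block 58 of 79 ribosomal protein, 46 of 54 oxidative phosphorylation and 9 of 28 ribosome biogenesis genes did. Lists not called also had such members, as with 6 of 18 glycolysis, 4 of 22 actin and 4 of 24 p53 target genes. With the block, 2791 of all 16066 genes had an unadjusted p under 0.05, and edgeR made 9.38% false calls in the simulations. Without Small 2 the respiration call ended (median 0.16), as did ribosome biogenesis (0.15), which also ended without Large 1 (0.09). Both lists were higher in number 1 than in number 2 (medians 0.52 and 0.32), which lowers the medians in these fits.

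HSC identity genes were lower in Large than in Small, and the primary granule and progenitor genes moved against them (0.82 within number 1 and 1.1 within number 2). The HSC identity list had a median log2 difference of -0.75 (-0.92 and -0.67; adjusted p = 1.7e-05, and 0.87 with an estimated correlation), with 25 of 30 members lower within both numbers, against 31.2% of all genes. Of the 30, 6 had both Large libraries below both Small libraries, near the 16.7% expected of interchangeable libraries. That needs Large 2 below Small 1, although these genes were lower in number 1 than in number 2. This count therefore cannot show that a shift is absent. Gata2, a transcription factor needed to maintain HSCs, had 95.8 ± 18.4 CPM in Large and 213 ± 48.8 in Small (log2 -1.15, SE 0.26). Mycn had 20.9 ± 1.82 and 48.6 ± 17.3 CPM (log2 -1.21, SE 0.41), and Tek, the angiopoietin receptor Tie2, had 26.4 ± 12.6 and 50.8 ± 18.4. Cell cycle inhibitors and quiescence genes had a median of -0.53 (-0.61 and -0.36; adjusted p = 0.0069, and 0.87 with an estimated correlation), with 12 of 18 lower within both numbers and 5 with both Large libraries below both Small libraries. Klf2 had 19.0 ± 3.19 and 32.0 ± 2.57 CPM, and the retinoblastoma-family gene Rbl2 had 100 ± 18.1 and 165 ± 44.7, whereas its relative Rbl1 had 130 ± 15.0 and 85.6 ± 10.9. No member of either list passed edgeR when adjusted over the list alone, but with the replicate block 15 of 30 and 8 of 18 did. The HSC identity call ended without Small 2 (median -0.19) or Large 1 (-0.06), and so did the quiescence call (-0.39 and -0.17). Each of these fits sets both numbers of one gate against 1 number of the other. HSC identity genes were lower in number 1 than in number 2 (median -0.78), which raises the median in both fits. These values therefore mix the size gates with the replicate numbers.

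Immediate early, interferon response and macrophage and dendritic genes were each called lower in Large by camera with the preset correlation. Immediate early genes, which respond within minutes to stimulation or cell handling, had a median of -0.62 (-0.87 and -0.41; adjusted p = 0.00016, and 0.64 with an estimated correlation), with 18 of 20 lower within both numbers and 6 with both Large libraries below both Small libraries. Jun had 793 ± 95.9 CPM in Large and 1250 ± 299 in Small (log2 -0.66, SE 0.22), and Zfp36, which encodes a protein that destabilises mRNAs, had 273 ± 151 and 548 ± 316. Interferon response genes had a median of -0.56 (-0.62 and -0.49, camera adjusted p = 0.00069, and 0.87 with an estimated correlation). Of 30, 22 were lower within both numbers. In 3, both Large libraries lay below both Small libraries, under the 16.7% expected of interchangeable libraries. Such genes need Large 2 below Small 1, and the list was lower in number 1 than in number 2 (median -1.08). The count of 3 therefore cannot show that a shift is absent. Stat2 and Irf9, partners in the interferon-activated transcription factor ISGF3, had 29.8 ± 14.3 against 57.5 ± 15.4 CPM and 76.6 ± 33.4 against 131 ± 47.4. The macrophage and dendritic list had a median of -0.44 (-1.23 and -0.11; adjusted p = 0.0069, and 0.87 with an estimated correlation), with 9 of 17 lower within both numbers and 4 with both Large libraries below both Small libraries, and the stricter filter ended the call (-0.49, adjusted p = 0.39). Its complement gene C1qb had 1.92 ± 0.113 and 6.78 ± 0.415 CPM, and Spic had 1.19 ± 0.269 and 7.14 ± 5.25. Again 0 members passed edgeR when adjusted over the list alone; with the replicate block 13 of 20 immediate early, 6 of 30 interferon and 0 of 17 macrophage and dendritic genes did. Without Large 1 the interferon median was 0.14 and the macrophage and dendritic median -0.04. Without Small 2 the interferon call ended (-0.11), and without Small 1 the macrophage and dendritic call ended (-1.39). Both lists were lower in number 1 than in number 2 (medians -1.08 and -0.43). This raises the medians without Large 1 or Small 2 and lowers them without Small 1.

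**Figure D2:**
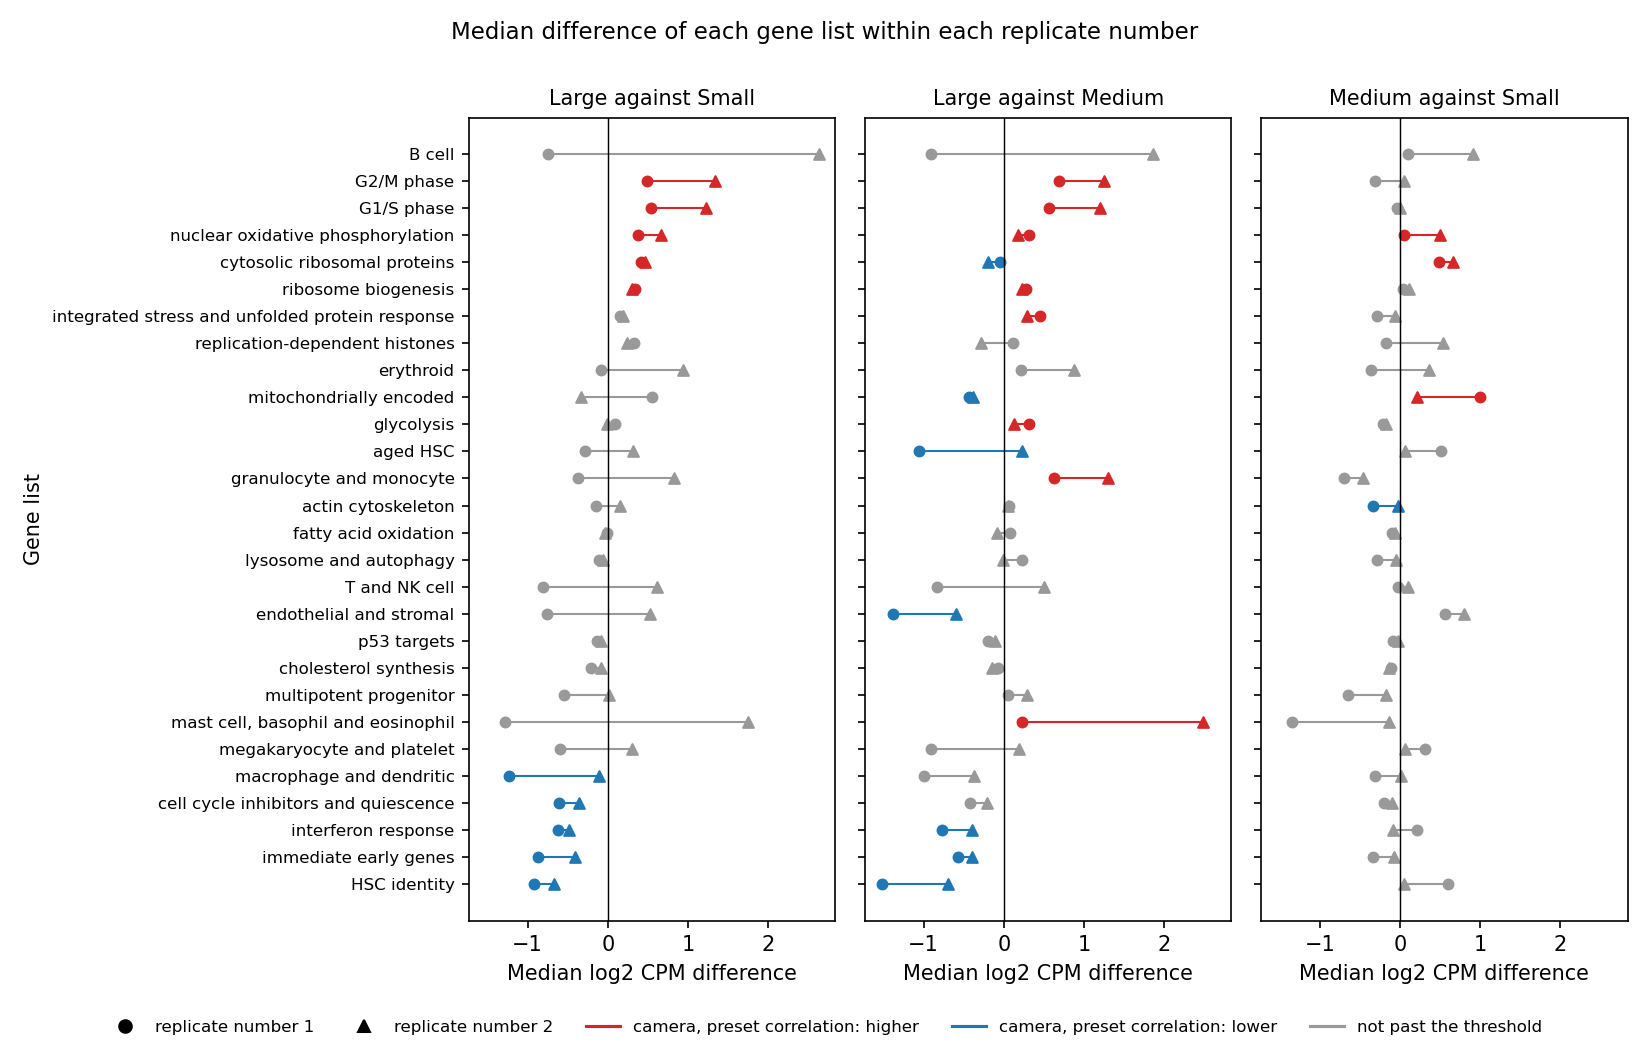
For each gene list (vertical) the horizontal axis gives the median difference in log2 CPM between 2 size gates, within replicate number 1 (circles) and number 2 (triangles), in 3 panels for the 3 pairs of gates; red and blue mark lists higher or lower by camera with the preset correlation, and grey those not past the threshold. In Large against Small the G1/S medians lie at 0.54 and 1.22 and the HSC identity medians at -0.92 and -0.67, and none of the coloured calls held with an estimated correlation.

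Several lists of other blood cell markers moved in opposite directions within the 2 replicate numbers. The B cell list had medians of -0.74 within number 1 and 2.63 within number 2 (adjusted p = 0.55), with 4722 summed CPM in Large 2 and 249 to 1618 in the other 7 libraries. Granulocyte and monocyte genes had medians of -0.37 and 0.82 (adjusted p = 0.55), and mast cell, basophil and eosinophil genes -1.28 and 1.75 (adjusted p = 0.55), with an overall median of -0.28 where the test pointed higher. Aged HSC genes had a median of 0.01 where the test pointed lower (adjusted p = 0.73). Erythroid genes (-0.08 and 0.94; adjusted p = 0.62), T and NK cell genes (-0.81 and 0.61; adjusted p = 0.55) and endothelial and stromal genes (-0.76 and 0.53; adjusted p = 0.80) were likewise not called. Multipotent progenitor, megakaryocyte and platelet, aged HSC, p53 target, glycolysis, fatty acid oxidation, cholesterol synthesis, lysosome and autophagy, integrated stress and unfolded protein response, actin cytoskeleton and histone genes did not pass, with adjusted p from 0.15 (actin) to 0.80 (fatty acid oxidation and histones). The B cell list was called higher without Large 1 (adjusted p = 2.8e-10) and lower without Large 2 (0.0021). Without Small 1 the granulocyte and monocyte (0.030), erythroid (0.030) and mast cell (0.0028) lists were called higher, and without Small 2 the megakaryocyte (0.00092) and actin (0.018) lists were called lower and the mitochondrially encoded list higher (0.00092), as it was without Large 2 (0.046).

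No single gene differed between Large and Small in the edgeR test (0 of 16066 genes; smallest adjusted p = 0.975). At an unadjusted p under 0.05 there were 506 genes, 285 higher and 221 lower, against 803 by chance. This fit leaves the differences between the replicate numbers in its spread, so a count under 803 does not mean fewer differences than chance. With the replicate number as a block in edgeR there were 2791, 1516 higher and 1275 lower, and the smallest adjusted p was 0.054. By other tools, DESeq2 called 10 genes, limma-voom 0, and limma-trend on the deposited log2(TPM + 1) values 1, Igkv12-89. With the block edgeR called 0, limma-voom 205 and DESeq2 1417. The immunoglobulin kappa variable segment Igkv12-89 (chromosome 6, 68834846 to 68835307) had 26.8 ± 1.57 CPM in Large and 0 in both Small libraries, at least 131-fold higher against a floor of 3 counts per library. Rif1, a regulator of replication timing (chromosome 2, 52072832 to 52122383), had 49.9 ± 9.62 and 16.6 ± 2.14 CPM (log2 1.59, SE 0.35). Mrtfa, a coactivator of serum response factor (chromosome 15, 81012281 to 81190757), had 31.1 ± 0.959 and 66.8 ± 2.21 CPM (log2 -1.11, SE 0.21). Gata2 lies on chromosome 6 at 88193891 to 88207032. DESeq2's 10 genes comprise Igkv12-89, 5 other immunoglobulin genes (Igkv8-24, Igkv14-126, Igkv16-104, Igha and Ighv11-2), Mrtfa, and the unnamed transcripts D930016D06Rik, Gm17134 and Gm10925. Several rest on 1 library: Igkv8-24 had 131 CPM in Small 1 and 0 in the 3 other Large and Small libraries, Igkv16-104 21.2 in Small 2 and 0 in the 3 others, Igkv14-126 624 in Large 2 and 0.286 in Large 1, Ighv11-2 353 and 0.214 in the same libraries, and Igha 113 in Small 1 and 2.64 in Small 2. Leaving out Large 1 lowered the number of genes at an unadjusted p under 0.05 to 151, leaving out Small 2 lowered it to 324, and leaving out Small 1 raised it to 800.

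**Figure D3:**
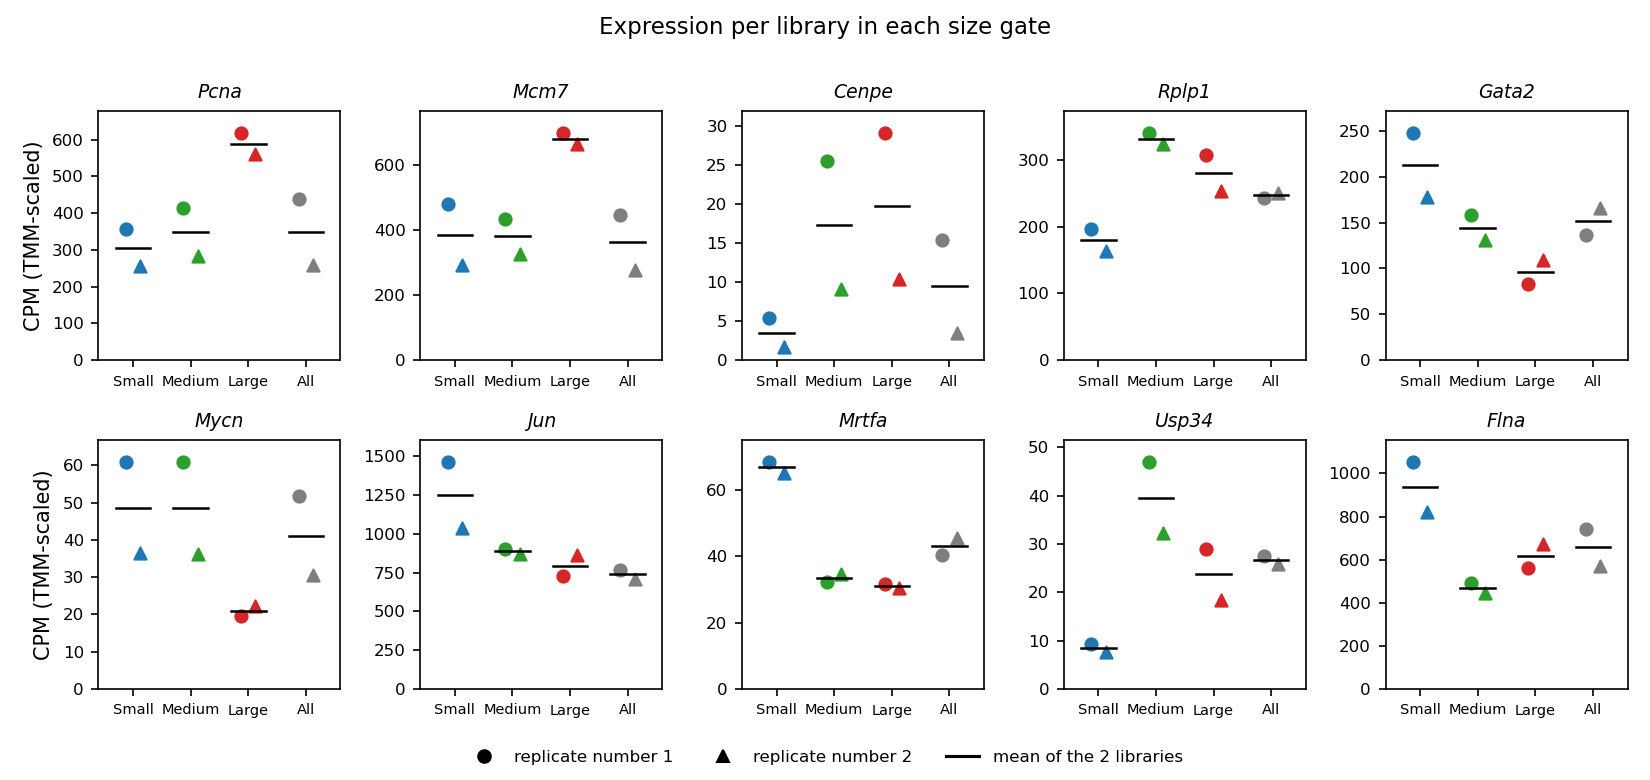
Each panel gives one gene's TMM-scaled CPM (vertical, from 0) in the Small, Medium, Large and All gates, with circles for replicate number 1, triangles for number 2 and a line at the mean of the 2 libraries. Pcna and Mcm7 have both Large libraries above both Small libraries, Gata2 and Mycn have both below, and none of the 10 genes passed the edgeR test between gates.

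Large and Medium HSCs differed in replication and HSC identity genes by camera with the preset correlation, and each adjusted p below is followed by the one with an estimated correlation. The HSC identity list had a median log2 difference of -0.90 (-1.52 and -0.70; adjusted p = 3.5e-09 and 0.685), with 26 of 30 members lower within both numbers, against 33.3% of all genes. G1/S genes were higher by a median of 0.76 (0.56 and 1.2; adjusted p = 3.7e-09 and 0.685), 26 of 30 of them within both numbers, and G2/M genes by 0.89 (0.68 and 1.25; adjusted p = 0.00023 and 0.685). Granulocyte and monocyte genes, which mark maturing myeloid cells, were higher by 0.90 (0.62 and 1.3; adjusted p = 0.0049 and 0.685), and mast cell, basophil and eosinophil genes by 0.98 (0.23 and 2.48; adjusted p = 0.039 and 0.685). Also higher were genes of ribosome biogenesis (0.26; 0.27 and 0.23; adjusted p = 0.0014 and 0.685), oxidative phosphorylation (0.25; 0.32 and 0.18; adjusted p = 0.00023 and 0.687), the stress responses (0.42; 0.45 and 0.29; adjusted p = 0.036 and 0.685) and glycolysis (0.19; 0.31 and 0.12; adjusted p = 0.039 and 0.685). Lower were interferon response genes (-0.49; -0.77 and -0.39; adjusted p = 0.00051 and 0.685), immediate early genes (-0.51; -0.57 and -0.40; adjusted p = 0.035 and 0.685), mitochondrially encoded genes (-0.43; -0.44 and -0.38; adjusted p = 0.0024 and 0.685) and aged HSC genes (-0.40; -1.05 and 0.22; adjusted p = 0.020 and 0.685). Ribosomal proteins (-0.12; -0.05 and -0.20; adjusted p = 0.018 and 0.718) and endothelial and stromal genes (-0.85; -1.38 and -0.60; adjusted p = 0.035 and 0.685) were lower too. All 15 calls were thus lost with an estimated correlation, and 0 members of any list passed edgeR when adjusted over the list alone. With the replicate block 20 of 30 HSC identity, 24 of 30 G1/S, 2 of 24 G2/M, 11 of 26 stress response, 9 of 18 glycolysis, 5 of 20 immediate early, 6 of 30 interferon and 1 of 30 aged HSC genes passed over their list, and 0 in the 7 other called lists. Among lists not called, 9 of 32 lysosome and autophagy genes passed as well. Also with the block, glycolysis (0.083), aged HSC (0.087) and endothelial genes (0.061) were no longer called, though their medians stayed at 0.18, -0.40 and -0.83 on log2 CPM. Megakaryocyte (0.043) and quiescence genes (0.010) were called lower with the block. Both of these calls were lost with the block and an estimated correlation (camera adjusted p = 0.68 and 0.67).

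HSC identity and G1/S genes were called between Large and Medium without any 1 library, and the 13 other lists were not. Leaving out Large 1 left 5 lists called: the calls ended for G2/M (adjusted p = 0.080), ribosome biogenesis (0.72), oxidative phosphorylation (0.73, median -0.00388), glycolysis (0.15), the stress responses (0.20), immediate early (0.34), interferon (0.86), granulocyte and monocyte (0.14), mast cell (0.15), aged HSC (0.32) and endothelial genes (0.52), and B cell genes were called higher (1.2e-08). Without Large 2 ribosomal proteins (0.74), mitochondrially encoded (0.34), glycolysis (0.12) and mast cell genes (0.078) were not called, though on the log2 CPM scale the glycolysis median went from 0.18 to 0.27 and the mast cell median from 1.48 to 1.56, while B cell (0.00010), macrophage and dendritic (0.014) and quiescence genes (0.0083) were called lower. Without Medium 1 aged HSC (0.92), ribosomal protein (0.31), mitochondrially encoded (0.31), glycolysis (0.47), stress response (0.24), immediate early (0.12) and endothelial genes (0.46, median -0.88 against -0.83 with all 8 libraries) were not called and erythroid genes were called higher (0.025), with 9 lists called. Without Medium 2, also with 9 called, the calls ended for G2/M (0.21), ribosome biogenesis (0.42), oxidative phosphorylation (0.12), the stress responses (0.071), immediate early (0.17), interferon (0.35), granulocyte and monocyte (0.28) and mast cell genes (0.82), and megakaryocyte and platelet genes were called lower (3.97e-05) and lysosome and autophagy genes higher (0.0065). Without Small 1 or Small 2 megakaryocyte genes were called lower (0.047), and without All 1 or All 2 glycolysis was not called (0.063). Differences between the numbers also enter the fits without a Large or Medium library. The lists not called with all 8 libraries had camera adjusted p from 0.065 (megakaryocyte) to 0.85 (B cell and p53 targets).

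Few single genes were called between Large and Medium without the replicate block. The edgeR test called 0 of 16066 genes, with 301 at an unadjusted p under 0.05, while DESeq2 called 2 (Igkv12-89 and Ighv1-80), limma-voom 0 and limma-trend 1 (Igkv12-89). Ighv1-80 had 0.0715 and 0.263 CPM in the Large libraries and 0 in both Medium libraries, which is near the floor of 3 counts. With the block, DESeq2 called 923 and edgeR and limma-voom 0, with 2380 genes at an unadjusted p under 0.05 in edgeR (smallest adjusted p = 0.076). Siah1b, a ubiquitin ligase (chromosome X, 164070705 to 164076493), had 51.5 ± 2.89 CPM in Large and 20.9 ± 2.41 in Medium (log2 1.3, SE 0.30), and Igkv12-89 had 26.8 ± 1.57 and 0.0308 ± 0.0435. Plekhg1 (chromosome 10, 3740364 to 3967303) had 1.95 ± 1.14 and 8.88 ± 1.94 CPM (log2 -2.18, SE 0.57), and the kinase gene Tnik (chromosome 3, 28263214 to 28675858) 9.66 ± 0.109 and 25 ± 1.0 (log2 -1.37, SE 0.37). None of these 4 passed (adjusted p = 0.989). Without Large 1 the number of genes at an unadjusted p under 0.05 was 110, and without Medium 2 it was 162.

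Ribosomal protein transcripts had a higher relative abundance in Medium than in Small HSCs. Granulocyte markers were lower in Medium within both numbers. Medians were -0.61 and -0.21 for the 5 primary granule and progenitor genes and -0.69 and -0.60 for 7 mature granulocyte genes. The ribosomal protein list was higher by a median log2 of 0.57 (0.49 and 0.66; adjusted p = 2.6e-26, and 0.75 with an estimated correlation), and 73 of 79 members had both Medium libraries above both Small libraries. Mitochondrially encoded genes were higher by 0.61 (0.99 and 0.21; adjusted p = 0.00047, and 0.75 with an estimated correlation) and nuclear oxidative phosphorylation genes by 0.24 (0.05 and 0.50; adjusted p = 0.027, and 0.91 with an estimated correlation). Actin cytoskeleton genes were lower (-0.18; -0.34 and -0.03; adjusted p = 0.027, and 0.75 with an estimated correlation). The G1/S (median -0.01; adjusted p = 0.94), G2/M (-0.20; 0.94, with the test in the other direction) and HSC identity lists (0.13; 0.16) were not called. The other 21 lists had adjusted p from 0.082 (lysosome and autophagy) to 0.92 (interferon response). In the 4 called lists 0 members passed edgeR when adjusted over the list alone. With the replicate block 70 of 79 ribosomal protein and 7 of 22 actin genes did, and 0 in the 2 respiration lists. Also with the block, HSC identity was called higher (0.045) and granulocyte and monocyte genes lower (0.046). Both respiration calls ended once each library's trends with GC content and transcript length were removed, to a median of 0.05 for mitochondrially encoded (adjusted p = 0.90) and 0.07 for nuclear genes (0.55). The actin call ended there too (0.053), though its median went from -0.18 to -0.27. Both respiration calls ended without Medium 1. Differences between the numbers enter this fit and the others here that leave out a Medium or Small library. Leaving out Small 1 left 2 lists called, and leaving out Small 2 or Medium 2 gave 9. Without Small 2, HSC identity (0.0082) and interferon genes (0.036) were called higher and G1/S (0.021), erythroid (0.033), granulocyte and monocyte (0.0013) and mast cell genes (0.0017) lower. Without Medium 2, G1/S (0.015), megakaryocyte (0.015), aged HSC (0.0031) and ribosome biogenesis genes (0.039) were called higher and lysosome genes lower (0.0034). Without Medium 1, G1/S (0.014), granulocyte and monocyte (0.014) and mast cell genes (0.028) were called lower, and without All 1 or All 2 granulocyte and monocyte genes were (0.016 and 0.015). Without Small 2 the nuclear respiration median was -0.05 (0.31), and without Small 1 the mitochondrial call (0.20) and the actin call (0.27) ended, as the actin call did without Medium 1 (0.13).

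Few single genes stood out between Medium and Small. Usp34, a deubiquitinase (chromosome 11, 23306895 to 23490560), had 39.6 ± 10.4 CPM in Medium and 8.49 ± 1.2 in Small (log2 2.22, SE 0.36). Lower in Medium were Mrtfa, with 33.4 ± 1.66 against 66.8 ± 2.21 CPM (log2 -1.0, SE 0.21), and the actin crosslinker Flna (chromosome X, 74223461 to 74249820), with 468 ± 34.4 against 937 ± 162 (log2 -1.0, SE 0.23). None passed the edgeR test, which called 0 of 16066 genes and found 695 at an unadjusted p under 0.05, or 0 and 2007 with the block (smallest adjusted p = 0.15). DESeq2 called 43, 35 higher and 8 lower, among them Usp34, Atrx, Tpr, Rif1 and Nipbl higher and Mrtfa lower; limma-voom and limma-trend called 0, and DESeq2 with the block 518. Without Medium 1 the number at an unadjusted p under 0.05 was 348.

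The fractions were set against All HSCs as the unseparated reference. Pmaip1 (chromosome 18, 66458533 to 66465565), which encodes the p53-induced apoptosis protein Noxa, had 79.5 ± 2.36 CPM in Small and 41.0 ± 3.91 in All (log2 0.95, SE 0.22). Large HSCs had 101 ± 5.27 CPM of it (log2 1.3, SE 0.22). Fut7, a fucosyltransferase that makes selectin ligands (chromosome 2, 25423267 to 25426374), had 40.5 ± 6.08 CPM in Small and 17.9 ± 2.64 in All (log2 1.18, SE 0.28). Medium HSCs had 14.6 ± 1.60 CPM of Igfbp7 (chromosome 5, 77349240 to 77408041) against 1.56 ± 1.34 in All, and 26.9 ± 3.70 of the matrix protein gene Sparc (chromosome 11, 55394500 to 55423183) against 5.03 ± 1.85; Sparc is also a member of the endothelial and stromal list. Ly75, an endocytic receptor (chromosome 2, 60292103 to 60383303), had 21.1 ± 4.07 CPM in Medium and 46.7 ± 8.20 in All, and Slc18a2, the vesicular monoamine transporter (chromosome 19, 59260896 to 59296012), had 60.9 ± 19.5 in Large and 152 ± 28.2 in All. The segment Igkv4-55 (chromosome 6, 69607275 to 69607828) had 31.2 ± 32.1 CPM in All, 0 in Small (at least 153-fold lower against the mean of All, and at least 41.6-fold against All 2 alone, which had 8.50 CPM where All 1 had 53.9), 0.432 ± 0.346 in Medium and 0.102 ± 0.0425 in Large, and Igkv12-89 had 26.8 ± 1.57 CPM in Large and 0.0844 ± 0.119 in All.

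None of these genes passed the edgeR test against All, which called 0 of 16066 genes in each of the 3 comparisons. At an unadjusted p under 0.05 it found 637 genes for Small, 262 for Medium and 504 for Large, against 803 by chance. Differences between the replicate numbers stay in the spread of this fit, so counts under 803 do not mean fewer differences than chance. With the block edgeR called 0 and found 1850, 845 and 3183 (smallest adjusted p = 0.28, 0.91 and 0.078). DESeq2 called 19, 6 and 8 genes, limma-voom 0 in each, and limma-trend 0, 0 and 1 (Igkv12-89); DESeq2 with the block called 369, 12 and 1622, and limma-voom with the block 0, 0 and 117. These counts rest on the All libraries: without All 1 the unadjusted counts were 1455, 938 and 1983, and without All 2 they were 331, 242 and 176. Without Large 1 the count for Large was 189, and without Medium 2 the count for Medium was 157.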

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

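Among the alternatives below, those that were chosen after seeing the data are DESeq2, limma-voom and edgeR at an adjusted p under 0.1 with the replicate block, the removal of GC and length trends, and the other list tests with the block. Library totals and DESeq2 size factors for the lists were also chosen after seeing the data, whereas those for single genes were planned. The edgeR count of 0 genes did not change in any of the 6 comparisons with DESeq2 size factors, library totals, the stricter filter, the 4 libraries of a pair, the block at 0.05, any 1 library left out (0 to 0) or trends removed, and limma-voom without the block also gave 0. Unadjusted counts, in the order Large against Small, Large against Medium, Medium against Small, then Small, Medium and Large against All, were 506, 301, 695, 637, 262 and 504, and with the block 2791, 2380, 2007, 1850, 845 and 3183. In that order the counts were 55, 58, 73, 69, 48 and 121 with no filter, 10, 2, 43, 19, 6 and 8 with DESeq2, and 1417, 923, 518, 369, 12 and 1622 with DESeq2 and the replicate block. Limma-trend on log2 TPM called 1 gene in Large against Small, 1 in Large against Medium and 1 in Large against All. With the block, limma-voom called 205 genes in Large against Small and 117 in Large against All, and edgeR at an adjusted p under 0.1 called 537 in Large against Small, 2 in Large against Medium and 559 in Large against All. DESeq2 with the block made 23.3% false calls in the simulations, so its counts are uncertain. The cause of these differences was not tested. The median difference of all genes was -0.14 in Large against Medium and -0.13 in Large against All under library totals, where TMM gave -0.013 and -0.034. On log2 TPM it was -0.11 in Large against Small and in Large against All, where TMM gave 0 and -0.034.

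The number of lists called (10, 15 and 4 in Large against Small, Large against Medium and Medium against Small) was 0, 0 and 0 with an estimated correlation, with fry, and with either of these and the block. In the simulations the estimated correlation found a shifted list in 0 of 5, so these counts do not separate a weak test from absent shifts. Leaving out 1 library gave 5 to 12 lists in Large against Small, 5 to 16 in Large against Medium and 2 to 9 in Medium against Small. With GC and length trends removed the last of these was 1. On log2 TPM, actin genes in Large against Small (adjusted p = 0.016), megakaryocyte and platelet genes in Large against Medium (0.036) and lysosome and autophagy genes in Medium against Small (0.030) were called lower and endothelial and stromal genes in Medium against Small higher (0.025). With the stricter filter, macrophage and dendritic genes in Large against Small (0.39), glycolysis in Large against Medium (0.072) and actin in Medium against Small (0.097) were not called, and megakaryocyte and platelet and quiescence genes in Large against Medium were called lower (0.025 each). With library totals, glycolysis (0.078) and endothelial and stromal genes (0.079) in Large against Medium and actin in Medium against Small (0.052) were not called. Of the alternative list medians, 366 kept direction and call, 180 kept direction and lost the call, and 5 reversed: interferon response in Large against Small without Large 1 (0.14; -1.27 without Large 2), ribosomal proteins in Large against Medium without Large 2 (-0.019, where the direction of the test changed to higher; without Large 1 the median was -0.27), oxidative phosphorylation in Large against Medium without Large 1 (-0.00388; 0.46 without Large 2) and in Medium against Small without Small 2 (-0.054; 0.64 without Small 1), and mitochondrially encoded genes in Medium against Small with trends removed and the block (0.048, where the direction of the test changed). In the fits without 1 library, differences between the numbers also enter the comparison. The cause was not tested.

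Of 2750 alternative values for 132 named genes and comparisons, 2567 kept direction and side of the threshold, 130 kept direction and passed it, and 53 had the other sign. The 53 belong to 25 genes in Large against Small, none past the edgeR threshold, and the cause was not tested. Values without 1 library include differences between the replicate numbers, because those fits have no term for the number. Below, each gene's lowest and highest values with 1 library left out follow its value with all 8. Lowest without Large 2 and highest without Large 1: Slamf1 (-0.04) -0.37 and 0.21 (0.13 without Small 1), Il7r (1.82) -4.33 and 2.79, Alas2 (0.46) -0.27 and 0.92, Vpreb3 (2.57) -0.98 and 3.48, Ebf1 (1.98) -0.97 and 2.85, Hbb-bt (-0.34) -1.32 and 0.21 (0.045 without Small 2), and Cavin1 (-0.34) -1.13 and 0.14. Lowest without Large 2 and highest without Small 2: Ly6a (-0.69) -3.03 and 1.18 (0.13 without Large 1), Cd27 (-0.62) -1.46 and 0.28, Ifit3 (-1.90) -3.72 and 0.041, and Emcn (-0.48) -2.37 and 0.72 (0.29 without Large 1). Lowest without Small 2 and highest without Small 1: Cd48 (0.41) -0.039 and 1.08, Myc (-0.36) -0.87 and 0.44, Hbb-bs (-0.52) -1.25 and 1.02, Csf1r (-0.46) -0.91 and 0.21, Cd3d (-1.44) -2.26 and 0.66, Epx (-1.04) -1.90 and 1.47, Ms4a2 (-0.66) -1.52 and 1.73, Fcer1a (-0.69) -1.69 and 9.81, and Cpa3 (-0.30) -1.15 and 2.05. Lowest without Large 1 and highest without Small 1: Nkg7 (0.72) -0.22 and 1.96, and Hist1h2ae (1.03) -0.34 and 2.06. With mt-Co2 (0.18) the lowest was -0.083 without Large 1 (-0.028 without Small 1) and the highest 0.42 without Small 2, and with mt-Nd5 (0.37) they were -0.093 without Small 1 and 1.05 without Small 2; mt-Nd4 (0.41) ran from 0.086 to 0.83.

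With limma-voom, Il7r was -0.30, Ms4a2 0.038, Fcer1a 2.79 and Cpa3 0.40; with limma-trend on log2 TPM, Alas2 was -0.027, Fcer1a 0.87 and Cpa3 0.24. With the replicate block in edgeR, Epx was 1.09, Ms4a2 0.44, Fcer1a 2.55 and Cpa3 0.51, and with the block in DESeq2 they were 1.35, 0.60, 3.89 and 0.55. With GC and length trends removed, Cd48 was -0.024, mt-Nd4 -0.069 and mt-Co2 -0.46. With trends removed and the block, mt-Nd4 was -0.029, mt-Co2 -0.41, Epx 1.16, Ms4a2 0.20, Fcer1a 2.08 and Cpa3 0.10. Depth limits genes at a few counts: 3 counts are 0.178 to 0.219 CPM over the libraries before TMM scaling.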

Other observations

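All tests here were chosen after the results they address had been seen. Libraries numbered 1 and 2 differed in 3947 genes in edgeR with terms for group and number, 1945 higher and 2002 lower in number 1. Flt3, a receptor of early progenitors, was lower in number 1 (log2 -3.71, adjusted p = 3.4e-05), as were Ly6a (-2.56), Procr (-2.46), Hlf (-2.01) and Cd34 (-1.66). The erythroid genes Gata1 (2.51) and Car1 (3.48) and the cycle gene Mki67 (1.5) were higher in number 1. By list, G2/M genes were higher by a median of 1.49 (camera adjusted p = 3.0e-09) and granulocyte and monocyte genes by 2.01 (4.1e-06), and HSC identity (-0.78, 6.4e-06) and interferon response genes (-1.08, 1.3e-09) were lower. All of these list calls were lost with an estimated correlation (adjusted p = 0.565 for interferon response and 0.614 for the others). Immunoglobulin transcripts added up to 7219 CPM in Large 2 and 308 to 2822 in the other 7 libraries.

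The split by replicate number was set against 3 technical explanations. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the split by number, gave as many genes (1935 without terms for group; the highest other gave 0), but only 8 of the 35 put 1 library of each group on either side, too few for a share under 0.05 among them. With GC and length trends removed 3664 genes were called, 3255 of them shared, so these trends are not the whole cause. A larger share of every other cell type in number 1 would raise their markers alike, but granulocyte and monocyte genes moved above B cell genes by 3.27 ± 1.16 (mean ± SD over 4 groups). The B cell medians ran from -4.17 in Large to 0.43 in All. A larger share of only some cell types is not addressed by this. Granulocyte and monocyte (mean 1.91), erythroid (1.71) and mast cell lists (2.42) were higher in number 1 in 4 of 4 groups. T and NK and endothelial lists were higher in 3 of 4, and macrophage and dendritic genes in 0. A difference in sort, animal or library day may underlie the split; the labels do not say what the number marks, and no biological explanation was tested.

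Cycle genes were called higher and HSC genes lower in Large than in Small by camera with the preset correlation. These calls were lost with an estimated correlation (camera adjusted p = 0.87 for G1/S, G2/M and HSC identity). The G2/M and HSC identity calls also ended without Small 2 or without Large 1, in fits where differences between the numbers also enter. A larger share of all other cell types in Large would raise their markers alike, but granulocyte and monocyte genes moved above macrophage and dendritic genes by 0.903 ± 0.0497 (mean ± SD over 2 numbers). This 1 pair of lists does not decide the question. Within number 2 the B (2.63), mast (1.75), erythroid (0.94), granulocyte and monocyte (0.82), T and NK (0.61) and endothelial lists (0.53) were higher in Large. Only macrophage and dendritic genes were lower there (-0.11). Within number 1 all of these lists were lower, from -1.28 for mast cell to -0.08 for erythroid genes. Mature granulocytes in the Large gate would raise mature granulocyte genes in both numbers, and their medians were -0.46 and 0.67, while primary granule and progenitor genes had 0.82 and 1.1. With GC and length trends removed, the 10 lists were called in the same direction, and an 11th, mitochondrially encoded genes, was called lower (-0.42, adjusted p = 0.022). The same 10 lists moved in the same directions in number 1 against number 2. Medians were 1.49 for G2/M, 0.73 for G1/S, 0.52 for oxidative phosphorylation, 0.32 for ribosome biogenesis and 0.16 for ribosomal proteins. HSC identity had -0.78, quiescence -0.60 and interferon response -1.08. Macrophage and dendritic (-0.43) and immediate early genes (-0.23) were not called. For these 10 lists the pattern thus runs along the unexplained difference between the numbers. Lists that were not called did not all do so. Mast cell genes had 2.58 between the numbers and -0.28 in Large against Small, and megakaryocyte genes 0.83 and -0.32. Erythroid genes had 0.94 and 0.12. Each gate holds 1 library of each number, so a number difference of equal size in both gates would not separate them. The size gate itself may account for the pattern, and a larger share of cycling progenitors in Large stays open and untested. The G0/1 gate and the sort on CD150, CD48, Sca-1 and CD117 are meant to exclude such cells, but the purity of the sorted cells was not measured here. Granulocyte and monocyte markers summed to between 4936 CPM (All 2) and 66293 CPM (All 1).

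DESeq2 called 35 genes higher in Medium than in Small. Of the 18 that are protein-coding and have no Gm number as name, 16 (88.9%) had transcripts longer than 5000 bases, against 21.7% of 8166 protein-coding genes with a mean log2 CPM over 4. With GC and length trends removed, their median Medium against Small was 1.78 in number 1 and 1.40 in number 2 (2.12 and 1.28 before), so these trends are not the whole cause. A general loss of long transcripts in Small would make the difference grow with length over all genes. The Spearman correlation was instead -0.039 in one number and -0.39 in the other. Another 749 genes, at least as long as the shortest of those 16 and within their highest GC content, had medians of 0.15 and -0.09. No upper bound on length or lower bound on GC content was set. These genes and the 8166 had a mean log2 CPM over 4, which was not required of the 18. A difference between size gates in these genes may remain, as a hypothesis found and tested on the same data.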
